A study of Mus musculus and Homo sapiens with 270 samples.

How the data were processed

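Messenger RNA was sequenced from intestinal tissue, epithelial layers and sorted immune cells of mice and from intestinal tissue and sorted immune cells of people. The labels' protocols describe cells sorted into lysis buffer, amplification by the Smart-seq2 method (full-length cDNA made by template switching), Nextera XT libraries and paired-end sequencing. No molecular identifiers are mentioned, so that reads copied by PCR cannot be told from separate molecules. Per the submitters' processing notes, FastQC, Salmon 1.4.0, R 4.3.2 and DESeq2 1.30.2 were used, with the genome builds mm10 and GRCh38. The annotation behind the gene models is not stated.

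The deposited tables hold 223 mouse columns over 57398 genes and 47 human columns over 63275 lines, of which 521 name no gene and hold at most 0.953% of the counts of any library. Those lines were left out of library sizes and tests. The authors deposited 4 kinds of values. For 173 columns the deposited values are estimated counts, not all of them whole, as Salmon gives them. For 54 columns of the palmitate experiment the authors deposited whole-number counts per gene. For 31 columns the deposited values sum to the same total, as TPM values (transcripts per 1000000) do. For 12 columns of regional MNP the authors deposited values in another unit, scaled in a way that no label states. Estimated counts were rounded to whole numbers before testing. Units were read from the values and the tools named, since the labels give no unit per column, and the plan had assumed counts in every column. Of the 57398 mouse Ensembl gene IDs, 52105 matched a symbol in GENCODE release M21, whose mm10 positions are used where a position is given. No table of human gene names was at hand, so human results are given as counts of genes without names.

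The gene order of the columns was checked before testing, by rank correlation across genes between columns of the same sets. In the ILC3 columns in TPM, 194 of 325 pairs of columns correlated at under 0.5, among them 4 of 25 pairs within a group, and the values ran from -0.01 to 0.94. In the MNP columns in TPM, 6 of 10 pairs lay under 0.5, none of them among the 4 pairs within a group. In the regional MNP columns 36 of 66 pairs lay under 0.5, none of them among the 6 pairs within a group, and between 1620 and 1688 of 57398 genes had a value above 0. Actb, B2m, Cd68, Csf1r and Eef1a1 are listed at 0 in all 12 of these regional columns. In the ILC3 columns the values do not sit beside the same genes throughout. In the MNP columns a common order could not be shown between groups, where a difference in order cannot be told from a difference in expression. No label gives another order. The 9 planned comparisons that rest on them were therefore not made, and 32 of the 41 planned comparisons were fitted, 28 in mouse and 4 in human. In the count columns of the palmitate experiment all pairs of ILC3 columns correlated at 0.86 or more and all pairs of MNP columns at 0.77 or more.

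A pair of columns titled ILC3 vehicle 1 and ILC3 stimulated palmitate 1 hold identical values (704377 counts), and so do the columns titled ILC3 stimulated vehicle 1 and MNP palmitate 4 (623848 counts). These 4 columns were left out, since no label says which title is right, and an alternative kept them under their titles. Seen later, levels given below argue against the titles ILC3 stimulated palmitate 1 and MNP palmitate 4. Groups were taken from the titles of the samples alone. The sample titled MNP vehicle 1 carries a cell-line label of ILC3 and was kept as MNP by its title. Seen later, its summed macrophage list (3584 CPM) lay beside those of vehicle libraries 2 and 3 (3330 and 3387 CPM).

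Comparisons of groups used edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr, robust dispersions, glmQLFit and glmQLFTest. Genes were called changed at a Benjamini-Hochberg adjusted p under 0.05, 2-sided. Libraries with fewer than 100000 counts were left out, which removed 6 libraries of the groups compared. All groups of a region or cell type at a given week entered a single fit. Epithelial layers were fitted over 4 regions with a term for the region. Human libraries of the same person, cell type and group were summed. Log2 fold changes are given with the standard error of the fit. Levels are CPM (counts per 1000000 counts) scaled by the TMM factors, as mean and SD over libraries. All adjusted p of single genes come from edgeR unless another tool is named, and all those of gene lists from limma's camera (limma 3.58.1).

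There were 30 gene lists, fixed with the design, the contrasts and the rule for named genes before the data were examined, and they cover lipid metabolism, defence, stress, proliferation and the cell types a sample could hold. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2, and again with a correlation estimated per list. For members of a list, the number past the threshold over all genes is given beside the number adjusted over the list alone. The rule for named genes took up to 10 rises and 10 falls of a comparison, by size of the fold change, among genes past the threshold with at least 5 CPM in the higher group and no overlap between the groups. It left out predicted genes, immunoglobulin and T cell receptor segments and mitochondrial and ribosomal genes. The 5 largest of each direction are printed, with 2 to 4 members per list past the threshold, and a few genes that the rule names are left out of the text. Where at most 10 genes changed all could be named, and a few defence, cytokine and lineage genes were fixed for every comparison of a kind. Where all libraries of a group held no count of a gene, a lower bound was computed against a floor of 3 counts over the group. Confidence intervals of shares are Wilson intervals at 95%. Such intervals and floors cover counting error only.

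Depth differed widely. Tissue libraries of 1 week held 18648 to 5344992 counts and those of 12 weeks 537 to 6240481. A single gene (ENSMUSG00000119584, without a symbol in the annotation used) led all 94 tissue libraries and took 75.3% to 97.0% of the counts in libraries of the germ-free and NAC experiments. The procedure was tested on simulated data made from the means and library sizes of the real samples. The simulated libraries were independent draws without sets of samples that differ. They therefore do not show how often structure among the real samples yields false calls. At 2 units of log2 fold change, 95.3% of the changed genes were recovered in jejunum at 1 week, 66.0% in jejunum of DIO mice and none in duodenum and ileum of DIO mice or in duodenum of Obese mice, with no call of the wrong sign in any comparison.

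Alternatives planned for each count were DESeq2 1.42.0 in place of edgeR, RLE factors in place of TMM, no filter on low counts, no depth minimum or a minimum of 1000000 counts, the sample number as a block, a term for sample numbers 1 to 3 against 4 to 6, only the 2 groups compared, the deepest library per person, a mean per region and leaving out each library in turn. Alternatives chosen after seeing the data were leaving out the leading gene, using only tissue libraries with little background (under 0.5% of counts in olfactory and vomeronasal receptor genes), thinning human counts to equal depth, using only human jejunum libraries with fewer than 20000 genes detected, and keeping the identical columns.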

Results

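The series measured gene expression by RNA sequencing in 223 mouse and 47 human libraries, to follow how a high-fat diet (HFD) acts on the intestine and its immune cells compared with a control diet (CD, titled chow). The mouse tissue libraries cover duodenum, jejunum, ileum and colon after 1 week of CD or HFD (6 libraries in each of 8 groups, 18648 to 5344992 counts). They also cover 12 weeks, with groups titled CD (2 libraries per region), DIO, for diet-induced obesity (3 per region), and Obese (3 per region), at 537 to 6240481 counts. No label says how DIO and Obese differ. Small intestine of HFD mice was sampled with water (5 libraries) or the antioxidant N-acetylcysteine, NAC (3 libraries), at 260047 to 2663664 counts, and small intestine of germ-free HFD mice with PBS or lipopolysaccharide, LPS (3 libraries each, 803953 to 1695371 counts). Libraries titled IEL, which the series design describes as epithelial layers, number 31 over the 4 regions (1934650 to 4180480 counts). In the palmitate experiment, group 3 innate lymphoid cells (ILC3, 15 libraries), mononuclear phagocytes (MNP, 15) and Th17 cells (24) received vehicle or palmitate, a saturated fatty acid, alone, with LPS or with a stimulus the labels do not name. These held 510288 to 823635 counts each. The human libraries come from jejunum (11 libraries, 331191 to 3380446 counts) and from sorted ILC3, MNP and Th17 (36 libraries, 362279 to 3882154 counts) of obese and lean people. A further 26 ILC3 and 17 MNP columns of mice were not compared, because a common gene order could not be shown for them, and 1 more ILC3 library, with 45065 counts, lay under the minimum of 100000.

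In duodenum after 1 week of HFD (6 HFD against 4 CD libraries) the class I histocompatibility gene H2-Q10 rose by 3.49 ± 0.35 log2 units, from 7.87 ± 2.21 CPM to 84.6 ± 34.4 CPM (adjusted p = 4.25e-05), and the laminin chain gene Lamb3 by 3.32 ± 0.39, with smaller rises of Cntnap1 (2.27 ± 0.43), Tubb2a (2.13 ± 0.38) and Kdelr3 (2.11 ± 0.38). Cyp2c29, a cytochrome P450, fell by 3.64 ± 0.57 and the glutathione transferase Gstm3 by 1.84 ± 0.35. Of 22 tested genes of fatty acid oxidation and ketogenesis, 1 rose over all genes and 8 when adjusted over the list alone (camera adjusted p = 2.35e-07, adjusted p = 0.245 with an estimated correlation). Of 15 genes of MHC class II and the interferon-gamma response, none fell over all genes and 5 fell when adjusted over the list alone (camera adjusted p = 3.14e-06, adjusted p = 0.0989 with an estimated correlation). In all, edgeR called 8 of 9148 genes, 6 higher and 2 lower, and 18 with a term for sample numbers 1 to 3 against 4 to 6. The count was 5 without CD library 2, 4 without CD library 3, 4 without HFD library 1, 3 without HFD library 2 and 3 without HFD library 3, and H2-Q10 and Lamb3 were past the threshold without any single library.

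In jejunum at 1 week (6 against 6 libraries) Apoc2, a cofactor of lipoprotein lipase, rose by 3.49 ± 0.58 log2 units, from 150 ± 110 CPM to 1705 ± 598 CPM (adjusted p = 0.0225). Rises were also called for Lamb3 (2.54 ± 0.36), the dynein gene Dnah2 (2.39 ± 0.33), malic enzyme Me1 (2.18 ± 0.41), the acyl-CoA dehydrogenase Acadl (2.09 ± 0.37), the lipid transporter Mfsd2a (1.92 ± 0.33), the fatty acid transporter Slc27a2 (1.53 ± 0.26) and Sec22c (1.48 ± 0.27). Igtp, an interferon-inducible GTPase, fell by 2.81 ± 0.53, the only fall. Over the list alone, 5 of 20 fatty acid oxidation genes rose (1 over all genes), with camera adjusted p = 6.27e-07 and adjusted p = 0.420 with an estimated correlation. Over the list alone, 11 of 16 MHC class II and interferon-gamma genes fell (none over all genes), with camera adjusted p = 8.71e-10 and adjusted p = 0.211 with an estimated correlation. Of 9510 genes, edgeR called 9, 8 higher and 1 lower, and with RLE factors 6 higher and 0 lower. With a term for sample numbers 1 to 3 against 4 to 6 it called 16. The count was 42 without CD library 6, 18 without HFD library 6, 5 without CD library 1, 3 without CD library 5 and 2 without each of HFD libraries 1, 2, 3, 4 and 5, with Lamb3 and Dnah2 past the threshold in all of these fits.

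In ileum (6 against 6 libraries) and colon (5 against 5) at 1 week edgeR called none of 11107 and 12341 genes, with 476 and 143 genes at an unadjusted p under 0.05 and 6 and 1 genes by DESeq2. In ileum, 5 of 20 fat absorption genes and 3 of 8 Paneth cell genes rose when adjusted over the list alone and none over all genes, with camera adjusted p = 1.35e-05 and 1.24e-07. Both list calls were lost at adjusted p = 0.520 with an estimated correlation. The test of whether the diet effect differs between the 4 regions called none of 20932 genes with edgeR, with 1016 at an unadjusted p under 0.05 and 28 by DESeq2, so that no difference between regions was shown for any named gene.

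In jejunum of DIO mice at 12 weeks (3 against 2 CD libraries) Apoa4 (ENSMUSG00000032080, chromosome 9, 46240696 to 46243459), an apolipoprotein of chylomicrons, rose by 4.31 ± 0.86 log2 units, from 325 ± 366 CPM to 6432 ± 2495 CPM (adjusted p = 0.0341). Apoc2 rose by 4.49 ± 0.74, the carnitine synthesis gene Bbox1 by 4.01 ± 0.69, Tm4sf4 by 3.60 ± 0.56, the peroxisomal thiolase Acaa1b by 3.50 ± 0.43 and the fatty acid binding protein gene Fabp1 by 3.48 ± 0.65. The fatty acid hydroxylase Cyp4a10 held 6.20 ± 3.41 CPM against 0.134 ± 0.189 CPM, the latter from 2 counts. Among fatty acid oxidation genes, 4 of 23 rose over all genes and 9 adjusted over the list alone, with Acadl at 1.31 ± 0.27 (camera adjusted p = 1.56e-08, adjusted p = 0.272 with an estimated correlation). Among fat absorption genes, 3 of 20 rose over all genes and 14 adjusted over the list alone (camera adjusted p = 1.37e-15, adjusted p = 0.308 with an estimated correlation). The gut hormone genes Sct and Gip rose by 1.83 ± 0.35 and 1.16 ± 0.26.

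Falls in DIO jejunum included immune and adipocyte genes. A changed share of such cells in the tissue was not separated from changed expression within them. H2-DMb1 (ENSMUSG00000079547, chromosome 17, 34153072 to 34160230), which loads peptides onto MHC class II, fell by 2.22 ± 0.31 log2 units, from 63.1 ± 10.6 CPM to 13.6 ± 1.90 CPM (adjusted p = 0.00297). Of 21 genes of MHC class II and the interferon-gamma response, 4 fell over all genes and 19 adjusted over the list alone, among them Gbp3 (-2.09 ± 0.44), Gbp2 (-1.58 ± 0.35) and H2-DMa (-1.41 ± 0.31) (camera adjusted p = 1.44e-13, adjusted p = 0.158 with an estimated correlation). Macrophage genes fell too, 3 of 16 over all genes and 5 adjusted over the list alone, with C1qb at -1.30 ± 0.24 and Csf1r at -1.23 ± 0.26, as did stromal genes, 2 of 12 and 9, with Dcn at -1.52 ± 0.31 (adjusted p = 0.158 with an estimated correlation for both). The chemokine gene Ccl8 fell by 3.83 ± 0.65, the granzyme gene Gzma by 2.63 ± 0.42 and Myc by 1.92 ± 0.26. The GTPase gene Gvin1, which has near-identical copies and is uncertain for that reason, was at least 160-fold lower, at no count in DIO. Of 6 tested adipocyte genes 2 fell over all genes, and 4 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00413, adjusted p = 0.343 with an estimated correlation). Cfd held 2 counts over 3 DIO libraries against 17.3 ± 19.9 CPM in CD (264 counts) and Adipoq 1 count against 6.42 ± 4.92 CPM (100 counts), levels that were uneven between the 2 CD libraries, and Car3 was 6.26 ± 0.99 log2 units lower. In all, edgeR called 155 of 14435 genes, 74 higher and 81 lower, and 39 of the falls were immunoglobulin segments. The count was 684 without CD library 2, 50 without CD library 1 and 90, 69 and 76 without DIO libraries 1, 2 and 3, and DESeq2 called 454. Of the 28 genes named from this comparison, 6 were past the threshold without any single library.

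**Figure D1:**
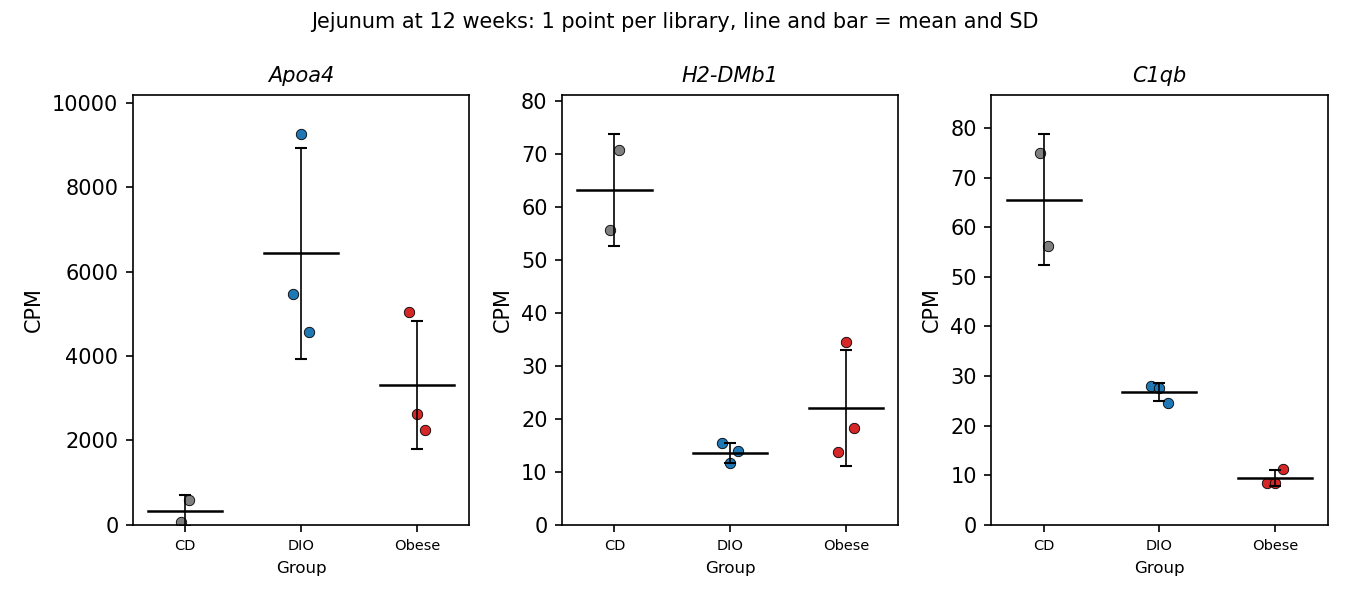
Levels of Apoa4, H2-DMb1 and C1qb in jejunum at 12 weeks, in CPM on linear axes from 0, with a point per library for CD (n = 2), DIO (n = 3) and Obese (n = 3), the line at the mean and the bar 1 SD. The 3 DIO libraries lie at 4559 to 9264 CPM of Apoa4 and the CD libraries at 65.8 and 583 CPM, while C1qb lies at 8.46 to 11.2 CPM in the Obese and at 56.3 and 75 CPM in the CD libraries.

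In ileum of DIO mice (3 against 2 libraries) all 16 called genes of 14258 were lower. Upk3b (ENSMUSG00000042985, chromosome 5, 136038496 to 136046487), a gene of the mesothelium, fell by 4.84 ± 0.73 log2 units, from 46.6 ± 11.4 CPM to 1.71 ± 2.26 CPM (adjusted p = 0.0003). Falls were also called for the complement gene C3 (-4.76 ± 0.85), the matrix genes Dcn (-4.08 ± 0.72) and Col3a1 (-2.95 ± 0.63), and the haemoglobin genes Hbb-bs (-6.12 ± 0.98) and Hba-a1 (-4.83 ± 0.72), which share reads with close copies and are uncertain. Aldh1a2 held 0.276 ± 0.309 CPM (2 counts) against 15.4 ± 1.32 CPM. As in jejunum, shares of cell types such as mesothelium were not separated from expression within cells. Of 20 MHC class II and interferon-gamma genes none fell over all genes and 15 adjusted over the list alone (camera adjusted p = 3.61e-19, adjusted p = 0.0712 with an estimated correlation). The count of 16 was 203 without CD library 1, 6 without DIO library 1 and 5 without DIO library 3, and 8 with RLE factors.

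The duodenum and colon of DIO mice gave few calls. In duodenum (3 against 2 libraries) edgeR called none of 18461 genes, with 190 at an unadjusted p under 0.05 and 13 by DESeq2. Of 12 genes of pancreatic acinar cells, which make digestive enzymes, none fell over all genes and 9 adjusted over the list alone (camera adjusted p = 1.00e-10, adjusted p = 0.612 with an estimated correlation). In colon edgeR called 3 of 13405 genes. The predicted gene Gm4617 fell by 5.18 ± 0.63 log2 units, the histone gene Hist2h2aa2, which has identical copies, was at least 247-fold lower and the unprocessed pseudogene Gm28437 at least 360-fold higher, the last 2 being uncertain as copies. The count was 0 without DIO library 2, CD library 1 or CD library 2, 6 without DIO library 3, and 71 with DESeq2. Scaling by RLE factors shifted the median of all genes by 0.16 log2 units in duodenum of DIO mice.

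In jejunum of Obese mice (3 against 2 CD libraries) 2567 of 14435 genes were called, 1283 higher and 1284 lower. These are tissue samples, and changed shares of cell types were not separated from changed expression within cells. Lyz2 and C1qb, genes of macrophages, fell by 3.48 ± 0.36 and 2.87 ± 0.28 log2 units and Csf1r by 2.17 ± 0.30, among 6 of 16 macrophage genes lower over all genes and 7 adjusted over the list alone (adjusted p = 0.274 with an estimated correlation). Of 21 MHC class II and interferon-gamma genes 16 fell over all genes and 18 adjusted over the list alone, led by Nlrc5 (-2.59 ± 0.48), Gbp2 (-2.58 ± 0.43) and Psmb9 (-2.14 ± 0.31) (camera adjusted p = 7.26e-09, adjusted p = 0.274 with an estimated correlation). Among cell cycle genes 18 of 20 fell over all genes and 19 adjusted over the list alone, with Ccnb1 at -2.59 ± 0.41, Aurkb at -2.06 ± 0.42 and Cdk1 at -1.92 ± 0.35 (adjusted p = 0.274 with an estimated correlation). The Paneth cell genes Mptx2 (-4.28 ± 0.59), Mmp7 (-3.13 ± 0.55) and Lyz1 (-2.39 ± 0.58) fell, with 5 of 8 members lower over all genes and 7 adjusted over the list alone (adjusted p = 0.533 with an estimated correlation). Of 12 B and plasma cell genes 7 fell over all genes and 9 adjusted over the list alone, such as Mzb1 (-3.26 ± 0.52) and Jchain (-2.96 ± 0.49) (adjusted p = 0.368 with an estimated correlation), and 92 immunoglobulin segments were lower. The defence lectin gene Reg3g (ENSMUSG00000030017, chromosome 6, 78466269 to 78468872) fell by 1.85 ± 0.59, from 2911 ± 1685 CPM to 807 ± 519 CPM (adjusted p = 0.0449).

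Rises in Obese jejunum included Fabp6, the ileal bile acid binding protein gene (ENSMUSG00000020405, chromosome 11, 43596049 to 43601540), by 7.92 ± 1.23 log2 units, from 4.24 ± 0.245 CPM to 1034 ± 838 CPM (adjusted p = 0.00434). For this ileal gene, the stretch of intestine sampled was not separated from an effect of the Obese condition. Of 20 fat absorption genes 7 rose and 1 fell over all genes, and 10 rose and 1 fell adjusted over the list alone, with Apoa4 at 3.35 ± 0.82, Slc27a4 at 2.85 ± 0.61 and the HDL receptor gene Scarb1 at -2.74 ± 0.71 (camera adjusted p = 5.15e-05, adjusted p = 0.574 with an estimated correlation). Vmn2r20, Xirp2, Olfr878, Olfr1489 and Vmn2r69 were at least 95.7-fold, 60.2-fold, 50.4-fold, 48.4-fold and 46.7-fold higher. All 5 held no count in CD and 27 to 47 counts over the 3 Obese libraries. Of the 1283 rises 71 were olfactory or vomeronasal receptor genes, families whose members share sequence and are uncertain, and none of the falls was. Tgtp1, uncertain for its copies, and the pseudogene Apol10c-ps, uncertain for the same reason, were at least 26.6-fold and 10.1-fold lower. Cfd, the gasdermin gene Gsdmc3 (0.157 ± 0.272 CPM) and the granzyme gene Gzmb (0.123 ± 0.212 CPM) held 1 count each in Obese, against 264, 155 and 117 counts in CD. The count was 556 without CD library 1, 1346 without Obese library 2 and 1300 when only Obese and CD entered the fit. Of the 44 genes named from this comparison, 25 were past the threshold without any single library.

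In ileum of Obese mice (3 against 2 libraries) 56 genes were called, 14 higher and 42 lower, and the peptide presenting genes of MHC class II were among the falls. H2-DMb1 fell by 4.09 ± 0.69 log2 units, Cd74 by 3.88 ± 0.82, H2-Ab1 by 3.73 ± 0.81 and H2-Aa by 3.61 ± 0.76, with 9 of 20 list members lower over all genes and 13 adjusted over the list alone (camera adjusted p = 1.65e-17, adjusted p = 0.0869 with an estimated correlation). Hba-a1, Hbb-bt and Hbb-bs were lower but uncertain, against the same 2 CD libraries as in DIO, which were uneven (Hbb-bs at 237 ± 261 CPM). Bcam held 0.109 ± 0.189 CPM (1 count) against 13.6 ± 5.56 CPM and the mesothelial gene Msln 0.803 ± 0.461 CPM (3 counts) against 23.0 ± 7.57 CPM. Shares of cell types were not separated from expression within cells here either. Acaa1b rose by 4.17 ± 0.91, Nlgn1 by 4.63 ± 1.05 and Bst1 by 3.41 ± 0.71, and the receptor genes Vmn2r67, Vmn1r193 and Olfr354 and the RNA gene Srsx, uncertain as copies, were at least 29.0-fold, 28.5-fold, 25.9-fold and 28.5-fold higher. The count was 339 without CD library 1, 27 without CD library 2, and 0, 4 and 14 without Obese libraries 1, 2 and 3. It was 37 with RLE factors (5 higher, 32 lower) and 0 when libraries with background were left out.

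In duodenum a single Obese library passed the depth minimum (222287 counts), and edgeR called no gene against 2 CD libraries, with 980 at an unadjusted p under 0.05 and 158 by DESeq2. Its spread was taken from the other groups, and RLE factors shifted the median of all genes by 0.48 log2 units there and by 0.11 in ileum of Obese mice. In colon the only gene called was Gm28437, at least 444-fold higher and uncertain as a copy, and it was lost without any single library of either group.

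The NAC comparison asks whether an antioxidant alters the HFD intestine. In small intestine under HFD with NAC (3 libraries) against water (5), Muc2 (ENSMUSG00000025515, chromosome 7, 141690340 to 141754693), the main gel-forming mucin, fell by 3.29 ± 0.69 log2 units, from 32.8 ± 29.4 CPM to 3.25 ± 0.480 CPM (adjusted p = 0.00199). The mucus protein gene Fcgbp fell by 4.02 ± 0.97 and Reg3g by 2.08 ± 0.49, from 82.6 ± 33.8 CPM to 19.9 ± 3.21 CPM. Of 6 antimicrobial and IL-22 target genes 1 fell over all genes and 4 adjusted over the list alone (camera adjusted p = 2.46e-04, adjusted p = 0.292 with an estimated correlation). The nuclear RNAs Malat1 (-3.40 ± 0.83) and Neat1 (2 counts with NAC, 30 with water), Ankrd17 (-3.93 ± 1.09) and D10Wsu102e (-3.18 ± 0.78) were lower, and the lectin-like gene Clec2h (1.91 ± 0.44) and the fatty acid binding protein gene Fabp2 (1.68 ± 0.44) rose. In all, 9 of 990 genes were called. The fold changes rest on unevenly scaled libraries. TMM factors ran from 0.169 to 6.83 with water and from 0.608 to 1.98 with NAC. Between 2568 and 13088 genes were detected with water and between 3901 and 12047 with NAC. The leading gene, which counted toward the depth minimum, took 78.3% to 97.0% of counts with water and 93.1% to 93.6% with NAC. The count was 2 with that gene left out. It was 5 without water library 3, 1, 2 and 0 without NAC libraries 1, 2 and 3, and 0 with no filter on low counts, and none of the 9 genes stayed past the threshold whichever library was left out. In germ-free HFD mice, LPS against PBS (3 against 3 libraries) gave no call among 986 genes with edgeR or DESeq2 and 45 genes at an unadjusted p under 0.05. That count was 1 without PBS library 2.

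Among genes fixed for all 14 tissue comparisons, Reg3g was past the threshold in 2 of 14 and its paralog Reg3b in none of 13 in which it was tested. The log2 difference of Reg3g was highest in ileum at 1 week, at 1.18 ± 0.58, as was that of Reg3b, at 1.32 ± 0.55. The lowest values, -3.02 ± 2.60 and -2.21 ± 2.57, rest on the single duodenum library of Obese mice, with 7 counts of each gene. H2-Ab1 was past the threshold in 2 of 12 (jejunum and ileum of Obese mice). The fatty acid translocase gene Cd36 was past it in none of 12, at -1.90 to 3.17. Il22 held at most 24 counts in any tissue group and was not tested.

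The epithelial layer libraries had the profile of epithelium, with Epcam at 175 ± 25.5 CPM and the T cell gene Cd3e at 0.605 ± 0.667 CPM in CD. Over 4 regions, HFD for 1 week (10 libraries) or 12 weeks (12) against CD (9) gave no call among 10978 genes with edgeR. The same CD libraries served both comparisons and their titles give no week, so that diet was not separated from time. At an unadjusted p under 0.05 there were 503 and 266 genes, and DESeq2 called 9 at 1 week and none at 12 weeks. Epcam differed by -0.01 ± 0.15 and 0.03 ± 0.14 log2 units. At 1 week, 6 of 7 B and plasma cell genes rose adjusted over the list alone and none over all genes (camera adjusted p = 6.74e-11, adjusted p = 0.0741 with an estimated correlation).

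Stimulation turned on the effector cytokines of ILC3 (2 stimulated against 3 vehicle libraries). Il22 (ENSMUSG00000074695, chromosome 10, 118204942 to 118210047), which acts on epithelium to induce defence, rose by 8.42 ± 0.11 log2 units, from 77.2 ± 10.2 CPM to 26493 ± 2351 CPM. Il17f rose by 7.65 ± 0.19, Ifng by 5.81 ± 0.43 and Il6 by 3.57 ± 0.34, Il17a was at least 73.8-fold and Il9 at least 21.2-fold higher, and Il33 rose to 137 ± 35.1 CPM from 2 counts over the vehicle libraries. Of 12 inflammatory and NF-kB genes 8 rose and 1 fell, over all genes and adjusted over the list alone, among them Cxcl2 (3.19 ± 0.18) and Nfkbia (2.12 ± 0.09) (camera adjusted p = 1.01e-07, adjusted p = 0.00884 with an estimated correlation). Of 12 lymphocyte activation genes 9 rose on both counts, such as Irf4 (3.16 ± 0.36), Myc (2.75 ± 0.31) and the IL-2 receptor gene Il2ra (2.39 ± 0.10) (adjusted p = 0.0630 with an estimated correlation). The antioxidant genes Hmox1 (2.77 ± 0.13) and Txnrd1 (1.91 ± 0.11) and the stress genes Chac1 (3.61 ± 0.56) and Trib3 (1.66 ± 0.27) rose, while the fatty acid gatekeeper Cpt1a (-1.84 ± 0.36) and the lipid droplet gene Plin2 (-1.74 ± 0.25) fell. Epithelial genes fell, 7 of 12 over all genes and 9 adjusted over the list alone with 1 rise, such as Lgals4 (-2.79 ± 0.49) (adjusted p = 0.130 with an estimated correlation), and Krt8, Cldn4, Acta1, Sprr1a and Eps8l3 were at least 27.5-fold, 19.3-fold, 13.0-fold, 8.87-fold and 6.01-fold lower. The summed epithelial list stood at 92.8 ± 21.5 CPM when stimulated and 312 ± 113 CPM with vehicle, and a lower share of epithelial RNA was not separated from an effect of stimulation. In all, 1552 of 8500 genes were called, 845 higher and 707 lower, against 988 by DESeq2 and 991 without stimulated library 3. All 28 genes named from this comparison were past the threshold without any single library.

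The palmitate comparisons ask what a saturated fatty acid does to these cells. In ILC3 (2 palmitate against 3 vehicle libraries) 2 of 8500 genes differed. The metallothionein gene Mt1 fell by 2.80 ± 0.56 log2 units, from 24.2 ± 15.4 CPM to 3.34 ± 2.80 CPM (adjusted p = 0.00603), and the guanylin gene Guca2a by 2.64 ± 0.58 (adjusted p = 0.0286). Guca2a is an epithelial gene, and the summed epithelial list also stood lower, at 209 ± 36.5 CPM with palmitate and 312 ± 113 CPM with vehicle (186 CPM in vehicle library 4), so that epithelial RNA was not separated from an effect of palmitate. Il22 differed by -0.33 ± 0.17, not past the threshold. The count was 17 without vehicle library 4, 0 without palmitate library 2, 4 with RLE factors and 0 by DESeq2. In stimulated ILC3 (2 against 2 libraries) palmitate raised Il22 by a further 0.30 ± 0.09, to 32535 ± 570 CPM (adjusted p = 0.0417). With the identical columns kept Il22 turned to -0.23 (adjusted p = 0.962) and 28 genes were called. That fit holds a column whose Il22 level argues against its title, as given below. Palmitate also raised the chaperone gene Hspa5 by 0.64 ± 0.11, Junb by 0.55 ± 0.11, Ptgs2 by 0.74 ± 0.17 and Icam1 by 0.57 ± 0.12. Larger rises were called for Itprip (2.57 ± 0.64), Lclat1 (2.35 ± 0.68), the kinase gene Eif2ak1 (1.96 ± 0.38), Snapin (1.92 ± 0.55) and Gtf2a1 (1.82 ± 0.46). Cbr1 and Chad were at least 4.10-fold and 3.65-fold lower, Car1 held 2 counts against 16, and Scn3a 1 count against 26. The summed epithelial list stood at 56.0 ± 1.48 CPM in stimulated palmitate and 92.8 ± 21.5 CPM in stimulated vehicle libraries. For the epithelial gene Car1, epithelial RNA was not separated from an effect of palmitate. Of 14 immediate early and heat shock genes 1 rose over all genes and 7 adjusted over the list alone (camera adjusted p = 0.0320, adjusted p = 0.236 with an estimated correlation). Of 120 calls, 87 were higher and 33 lower. The count was 79 and 19 without stimulated palmitate libraries 2 and 3 and 61 and 45 without stimulated vehicle libraries 2 and 3, and 60 by DESeq2. Only Eif2ak1 and Hspa5 of the 14 genes named from this comparison were past the threshold without any single library.

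ILC3 libraries with LPS on top of palmitate (3 against 2) held more RNA of epithelial genes, and RNA from colon epithelial cells was not separated from a response to LPS. Epcam (ENSMUSG00000045394, chromosome 17, 87635979 to 87651129), an adhesion gene of epithelium, rose by 3.46 ± 0.28 log2 units, from 18.8 ± 4.11 CPM to 209 ± 16.1 CPM (adjusted p = 1.19e-28), with Lgals4 at 3.71 ± 0.28, Krt20 at 3.06 ± 0.65 and Krt18 at 2.88 ± 0.36. Of 12 tested epithelial genes 11 rose, over all genes and adjusted over the list alone (camera adjusted p = 7.55e-24, adjusted p = 0.0178 with an estimated correlation). Of 5 antimicrobial genes 3 rose on both counts, with Muc13 at 4.08 ± 0.41 and the immunoglobulin transporter gene Pigr at 4.03 ± 0.40 (adjusted p = 0.0623 with an estimated correlation). The summed pancreatic acinar list also stood higher, at 51.1 ± 15.9 CPM against 14.1 ± 2.62 CPM. Atp12a, Spint1, Saa1, Clec2h and Fhl1 were at least 30.0-fold, 18.4-fold, 15.6-fold, 12.7-fold and 9.02-fold higher. Falls were called for the cytokine receptor gene Csf2rb2 (-2.22 ± 0.61), Gbp7 (-0.80 ± 0.23), Metap2 (-0.74 ± 0.22), Gbp4 (-0.62 ± 0.15) and Serpina3g (-0.56 ± 0.15). Il22 differed by -0.42 ± 0.19, not past the threshold. Of 162 calls, 157 were higher. The count was 97 and 91 without palmitate libraries 1 and 2 and 85 by DESeq2.

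**Figure D2:**
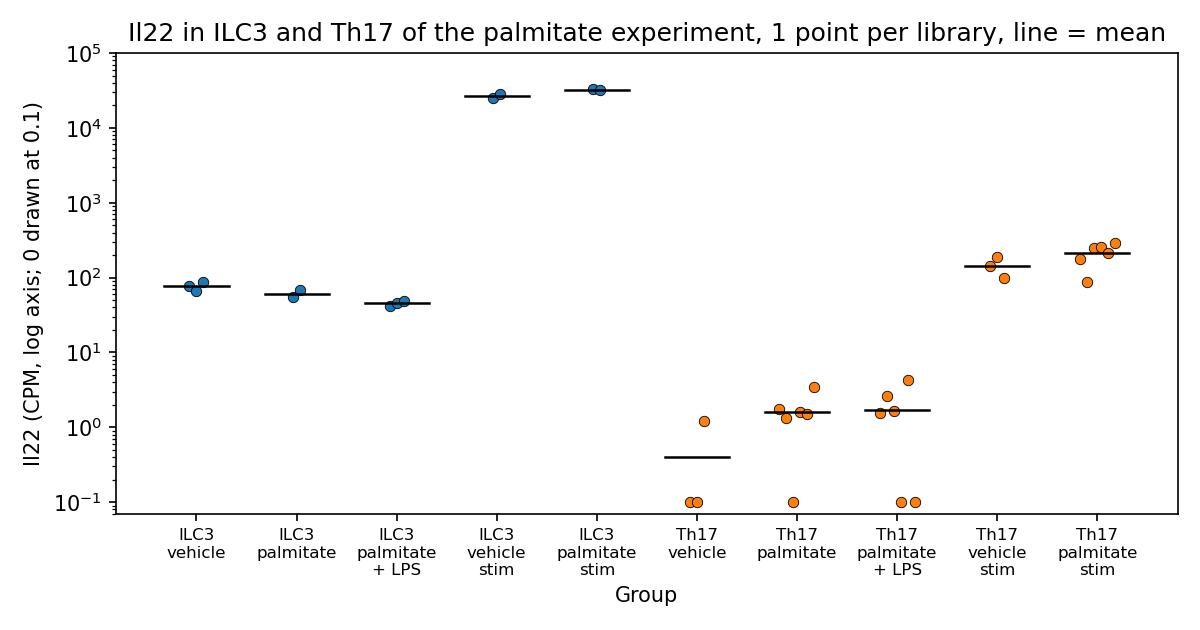
Il22 in ILC3 and Th17 of the palmitate experiment, in CPM on a log axis, with a point per library (n = 2 to 6), values of 0 drawn at 0.1 and a line at the mean. The stimulated ILC3 libraries lie at 24831 to 32939 CPM and the unstimulated ones at 41.8 to 87.4 CPM, and the stimulated Th17 libraries at 87.6 to 288 CPM and the unstimulated ones at 0 to 4.3 CPM.

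In MNP palmitate (5 against 3 vehicle libraries) lowered cholesterol synthesis genes and raised a lipid droplet gene. Plin2 (ENSMUSG00000028494, chromosome 4, 86648386 to 86670060), a coat protein of lipid droplets, rose by 1.11 ± 0.20 log2 units, from 307 ± 14.6 CPM to 661 ± 122 CPM (adjusted p = 0.000686). Fdps, Msmo1, Fdft1 and Cyp51, enzymes of the sterol pathway, fell by 1.79 ± 0.27, 1.79 ± 0.22, 1.47 ± 0.30 and 1.46 ± 0.23. Of 19 genes of sterol and fatty acid synthesis 7 fell over all genes and 11 adjusted over the list alone (camera adjusted p = 6.93e-17, adjusted p = 0.0079 with an estimated correlation). The desaturase gene Scd2 fell by 1.67 ± 0.37 and Il12b, a subunit of IL-12 and IL-23, by 3.06 ± 0.64. With palmitate Il12b held 6 counts over the 5 libraries (1.62 ± 1.22 CPM). Rises were called for Thap12 (2.57 ± 0.58), Serpinb2 (1.37 ± 0.24), Arl4c (0.93 ± 0.21) and Tiparp (0.87 ± 0.17). Tnf differed by 0.03 ± 0.20, Il1b by -0.08 ± 0.20 and Cd68 by -0.19 ± 0.20, none past the threshold. In all, 24 of 8477 genes were called, 6 higher and 18 lower. The count was 13 and 15 without vehicle libraries 1 and 2 and 43 without palmitate library 2, and 13 with the identical column kept.

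LPS with palmitate against palmitate (6 against 5 libraries) induced the inflammatory genes of MNP. Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) rose by 2.78 ± 0.17 log2 units, from 280 ± 68.6 CPM to 1915 ± 274 CPM (adjusted p = 6.07e-17), and Il1b by 2.37 ± 0.17. The largest rises were those of the chemokine gene Cxcl1 (3.88 ± 0.23), Il12b (3.49 ± 0.55), the iron-binding defence gene Lcn2 (3.31 ± 0.25), Saa3 (3.29 ± 0.22) and Il1a (3.16 ± 0.17). The rise of Il12b starts from the same 6 counts with palmitate as its fall above, so that these 2 changes are not independent. Of 20 inflammatory genes 17 rose over all genes and 18 adjusted over the list alone (camera adjusted p = 4.31e-38, adjusted p = 0.000192 with an estimated correlation), and of 6 antimicrobial genes 4 rose on both counts (adjusted p = 0.00338 with an estimated correlation). Lpl, the lipase that releases fatty acids from lipoproteins, fell by 2.25 ± 0.15, the collagenase gene Mmp8 by 2.15 ± 0.26, and Gimap3, Tifab and Il21r by 2.36 ± 0.47, 2.18 ± 0.32 and 2.10 ± 0.23. Of 13 macrophage genes 5 fell and 1 rose over all genes, and 6 fell and 2 rose adjusted over the list alone, with the chemokine receptor gene Ccr2 at -1.27 ± 0.21, Lyz2 at -1.09 ± 0.17 and Csf1r at -0.93 ± 0.14 (adjusted p = 0.189 with an estimated correlation). With the identical column kept this list turned direction (adjusted p = 0.298). That column holds 3 counts of Cd68 and 0 of Lyz2, so that the turn does not bear on the LPS effect. Cd68 differed by -0.32 ± 0.17, not past the threshold. In all, 482 genes were called, 286 higher and 196 lower, and 144 with the identical column kept.

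**Figure D3:**
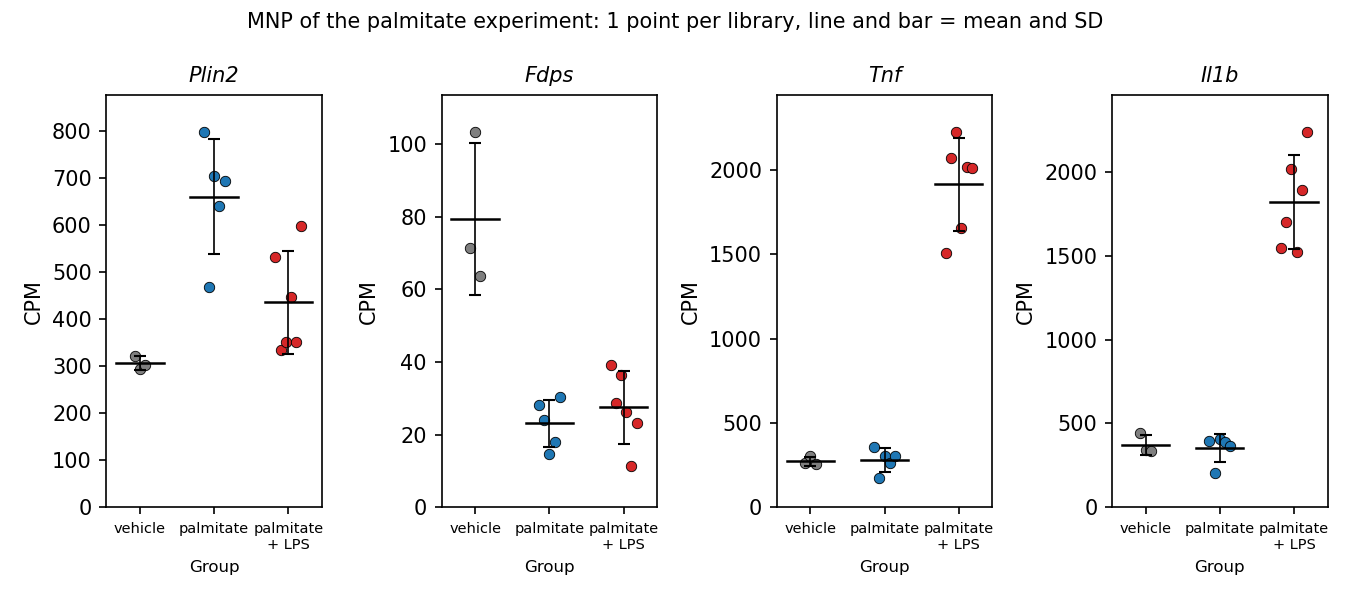
Levels of Plin2, Fdps, Tnf and Il1b in MNP of the palmitate experiment, in CPM on linear axes from 0, with a point per library for vehicle (n = 3), palmitate (n = 5) and palmitate with LPS (n = 6), the line at the mean and the bar 1 SD. Fdps lies at 63.7 to 103 CPM with vehicle and at 14.8 to 30.4 CPM with palmitate, and Tnf at 1508 to 2224 CPM with LPS and at 172 to 354 CPM with palmitate alone.

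In Th17 cells palmitate (6 against 3 vehicle libraries) raised Cpt1a (ENSMUSG00000024900, chromosome 19, 3322334 to 3385733), which admits fatty acids to mitochondria, by 1.19 ± 0.17 log2 units, from 53.8 ± 13.0 CPM to 123 ± 22.1 CPM (adjusted p = 1.67e-07). The glucocorticoid-induced gene Tsc22d3 fell by 0.61 ± 0.11, Adgre5 by 0.53 ± 0.12 and mt-Nd1 by 0.33 ± 0.07. Of 15 fatty acid oxidation genes 1 rose over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00154, adjusted p = 0.00872 with an estimated correlation). These 4 of 8183 genes became 2 without vehicle library 2, vehicle library 3 or palmitate library 5. LPS with palmitate against palmitate (6 against 6) lowered Gbp2 (-0.63 ± 0.11) and Irgm1 (-0.68 ± 0.14), genes of the interferon response. The immunoglobulin segment Ighv1-26 was higher (4.03 ± 0.59), with 76 counts against 4. The summed B and plasma cell list stood at 369 ± 111 CPM with LPS and 336 ± 124 CPM with palmitate. For Ighv1-26, RNA of B cells was not separated from an effect of LPS. Of 16 MHC class II and interferon-gamma genes 2 fell over all genes and 3 adjusted over the list alone (camera adjusted p = 8.47e-05, adjusted p = 0.0104 with an estimated correlation). The 3 genes named were past the threshold without any single library, and the count was 7 without palmitate library 6.

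Stimulated Th17 cells (3 against 3 vehicle libraries) held 144 ± 44.7 CPM of Il22 against 0.402 ± 0.696 CPM, the latter from 1 count (adjusted p = 1.49e-06). Rises were called for the transporter gene Slc2a6 (2.09 ± 0.42), Bcl3 (1.84 ± 0.38), the prostaglandin receptor gene Ptger2 (1.35 ± 0.34), Mrpl21 (33.1 ± 5.61 against 13.6 ± 3.14 CPM), Gbp2 (0.97 ± 0.13) and Nfkbia (0.77 ± 0.10). Falls were called for Matk (-1.25 ± 0.30), Zfp866 (-1.20 ± 0.32), Mturn (-0.81 ± 0.20), the phosphatase gene Ptpn22 (-0.79 ± 0.14) and Ddx50 (-0.69 ± 0.18). Of 16 MHC class II and interferon-gamma genes 4 rose over all genes and 6 adjusted over the list alone (adjusted p = 0.00389 with an estimated correlation), and of 6 inflammatory genes 2 and 3 (adjusted p = 0.00268 with an estimated correlation). In all, 44 genes were called, 34 higher and 10 lower, with 29, 14 and 26 without vehicle libraries 1, 2 and 3 and 20 without stimulated library 2. Palmitate in stimulated cells (6 against 3) raised Pim2 by 0.76 ± 0.16 and Ssh2 by 0.44 ± 0.10 (adjusted p = 0.0430 for both), and Il22 differed by 0.50 ± 0.23, not past the threshold. DESeq2 called neither of these 2 genes, and the count was 0 without stimulated palmitate library 1 or 3 or stimulated vehicle library 3, and 1 without stimulated palmitate library 4 or stimulated vehicle library 1 or 2. The palmitate effect differed between stimulated and unstimulated Th17 cells for none of the genes with edgeR or DESeq2, with 358 at an unadjusted p under 0.05. Il17a, Il23r and Ahr held at most 2, 25 and 33 counts in a Th17 group and were not tested.

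The human comparisons ask how obese and lean people differ in the same cells, and gene names were not available for them. In jejunum (5 obese against 6 lean people) 1513 of 8488 genes were called, 222 higher and 1291 lower in the obese group. The obese libraries detected 15391 to 18589 genes and the lean ones 17098 to 40110, with 1 of the lean under 20000, and the count was 602 with counts thinned to equal depth. It was 7 with a minimum of 1000000 counts (3 against 2 people left). In ILC3 (7 against 3 people) 637 of 18203 genes were called, 54 higher and 583 lower, with 203 for thinned counts and 12 at the minimum of 1000000 counts (3 against 3 people left). In MNP (5 against 2) 74 of 11962 were called, 41 higher and 33 lower, and 118 with thinned counts. In Th17 (4 against 2) 5515 of 10814 were called, 2979 higher and 2536 lower, and 2775 with thinned counts. The obese Th17 libraries held 362279 to 626562 counts and the lean ones 1813908 to 2210997. Summed per person as fitted, the 2 lean people held 2093090 and 6156320 counts. RLE factors shifted the median of all genes by -0.18 log2 units. Leaving out each person in turn gave 571 to 3943 genes in jejunum, 151 to 970 in ILC3, 21 to 359 in MNP and 1752 to 5838 in Th17. In jejunum the 3943 came without lean person 1, whose library detected 17098 genes. Without lean people 2, 3, 4 and 5 the jejunum count was 571, 577, 750 and 712, and without lean person 6 it was 1971. Leaving out an obese person gave 2687 to 3680.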

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

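The tests with colon epithelial genes, of the receptor share against library totals, of the Obese condition, of thinned counts and of other splits were chosen after the result was seen. The other tests below were written down before. Of 69 groups and measures examined for a sample far from the others, 5 exceeded the critical value, where chance alone gives 3.45. H2-Ab1 of jejunum CD library 6 at 1 week lay at 3.48 log2(CPM + 1), the other 5 at 7.86 to 8.94, and this is the library without which 42 genes were called in that comparison. Il22 of ileum HFD library 3 at 1 week lay at 2.30, the others at 0 to 0.510. In the palmitate experiment, Il1b of MNP palmitate library 2 lay at 7.61 (others 8.46 to 8.61), Cd68 of MNP palmitate with LPS library 6 at 8.27 (others 7.61 to 7.85) and Ahr of Th17 palmitate library 4 at 3.72 (others 2.64 to 3.03). No cause was tested for these 5 samples.

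Columns that no comparison used held signals of the cytokine Il22. The library titled ILC3 SPF Fish 3, which came as counts (45065 in all), held Il22 at 488 CPM (interval 322 to 739, 22 counts), above the 66.6 CPM that 3 counts would give, and also 28 counts of the epithelial gene Fabp1. The column titled MNP palmitate 4, identical to that titled ILC3 stimulated vehicle 1, held Il22 at 20801.5 CPM (20450 to 21159, 12977 counts), 3 counts of Cd68 and 0 of Lyz2. The 5 MNP palmitate libraries used held Cd68 at 294 ± 99.1 CPM and Lyz2 at 602 ± 187 CPM. These values argue against the title MNP palmitate 4, and the Il22 level is near that of stimulated ILC3 libraries. No label settles which title is right.

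The rise of epithelial genes in ILC3 with palmitate and LPS was weighed first. Of 345 jejunum genes 100 (29.0%) were higher in every LPS library, where chance gives 10%. The median gain was 0.407% of the jejunum level, too little to show for genes near the 100 CPM minimum, so that this share alone cannot decide. The values argue against RNA from jejunal epithelial cells, since abundant jejunum genes stayed low (Apoa1 at 0 CPM against 14387 CPM in jejunum, Fabp2 at 2.57 CPM against 9102 CPM). For RNA from MNP, 8 of 92 MNP genes (8.70%) were higher, where chance gives 10%, a share that cannot decide alone for the same reason. The summed macrophage list stood at 69.0 ± 5.69 CPM with LPS and 81.9 ± 2.47 CPM with palmitate. It was thus not higher with LPS, which argues against RNA from MNP. RNA from colon epithelial cells cannot be told apart from a response to LPS, since 51 of 99 colon genes (51.5%) were higher, such as Car1 (121 ± 18.2 against 2.65 ± 0.0788 CPM), Aqp8 (31.7 ± 3.09 against 0.648 ± 0.917 CPM) and Lypd8 (601 ± 15.3 against 19.8 ± 3.15 CPM), while Muc2 stayed at 2.50 CPM against 25667 CPM in colon. LPS itself remains open as an untested biological explanation.

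Olfactory and vomeronasal receptor counts in tissue libraries were weighed next, as such genes are silent outside sensory tissue. Background in libraries with few transcripts passed its test, since within groups the receptor share fell with the total without the leading gene (Spearman -0.851, Pearson -0.870, n = 73, permutation adjusted p = 1e-05 over 2 relations). Without the 2 most extreme libraries the values were -0.838 and -0.838. Background that also reaches other silent gene families passed too, since the receptor share rose with that of hair keratin-associated genes (Spearman 0.882, Pearson 0.931, permutation adjusted p = 1e-05, without the 2 extremes 0.872 and 0.914). The receptor and keratin shares are both taken over the total without the leading gene. A fall with that total, and a rise of 1 share with the other, are therefore partly built in. The 2 relations are also not independent of each other. The permutations do not remove this, so that these tests alone cannot decide on background. The values argue against the Obese condition as the whole cause, since 31 of 64 other libraries reached the lowest Obese jejunum library and 2 of 10 Obese libraries lay at or below a CD library of their region. Whether Obese adds to background in jejunum (0.0547% to 1.09%, CD 0.00783% to 0.00954%) stays open.

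The excess of falls over rises in human jejunum was weighed last. The values argue against a difference in total counts as the whole cause, since 602 genes, 80 higher and 522 lower, were called with counts thinned to equal depth, which did not match the number of genes detected. Background in libraries that detect many genes was tested by the share of falling genes under 5 CPM in the obese group, 373 of 1291 (28.9%). That test cannot decide, since only 453 of 8488 tested genes lay there, too few to hold most of the falls. Background stays open, since 5.34% of all tested genes and 0 of 222 rises lay under 5 CPM. The count was also highest (3943) without lean person 1, the lean person with the fewest genes detected. It fell to 571, 577, 750 and 712 without lean people 2, 3, 4 and 5. Obesity itself stays open as a biological explanation, but 5 of 100 splits of these 11 people gave as many calls, so that chance is not excluded (1513 genes, highest other split 2985).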

How the results depend on the processing

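Alternatives chosen after seeing the data were those without the leading gene, with little background, with thinned counts, with fewer than 20000 genes detected and with the identical columns kept. Of 204 counts recomputed under alternatives that leave out no single library, 109 stayed within 1.5 times the reported count and 95 moved, and the cause was not tested except where stated. Of 261 fits without a single library 91 moved. Depth limits the tissue, since counts ran from 18648 to 5344992 at 1 week and the leading gene took up to 97.0% of a library. Groups of 2 or 3 libraries left the 12 week counts at the mercy of single libraries. In fits that leave a group with 1 library, that library is assumed to vary like the other groups. DESeq2 gave for the tissue 24 genes in duodenum, 49 in jejunum, 6 in ileum and 1 in colon at 1 week, 13, 454 and 71 in duodenum, jejunum and colon of DIO mice, and 158, 85 and 2 in duodenum, ileum and colon of Obese mice. It gave 3026, 1164 and 366 in human jejunum, ILC3 and MNP, 9 in epithelial layers at 1 week and 28 for the difference between regions. In the palmitate experiment it gave 0, 85, 988 and 60 in ILC3 with palmitate, with LPS, when stimulated, and with palmitate when stimulated, and 0 in stimulated Th17 with palmitate.

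With no filter on low counts, which tests more genes, duodenum and jejunum at 1 week gave 78 and 46 genes, duodenum, jejunum, ileum and colon of DIO mice 84, 460, 46 and 223, duodenum and colon of Obese mice 2 and 9, NAC 0 and germ-free LPS 11. Human jejunum, ILC3 and MNP gave 12269, 1608 and 592, epithelial layers 26 and 8 at 1 and 12 weeks, and Th17 12 with LPS, 8 when stimulated and 0 with palmitate when stimulated. With no depth minimum the counts were 20 (duodenum at 1 week), 373 (duodenum of Obese mice) and 5 (difference between regions). With a minimum of 1000000 counts, which leaves fewer libraries, they were 16 and 40 (duodenum and jejunum at 1 week), 0 (ileum of Obese mice), 2 (NAC), 7 and 12 (human jejunum and ILC3) and 6 (difference between regions). RLE factors gave 8 and 37 (ileum of DIO and of Obese mice), 4 (ILC3 with palmitate) and 3 (difference between regions). The term for numbers 1 to 3 against 4 to 6 gave 18 and 16 (duodenum and jejunum at 1 week) and 3 (difference between regions). Only the groups compared gave 1 (colon of DIO mice), 1300 (jejunum of Obese mice), 37 (stimulated ILC3 with palmitate), and 7, 26 and 1 (Th17 with LPS, stimulated, and stimulated with palmitate). Libraries with little background gave 14 and 36 (duodenum and jejunum at 1 week), 292 and 7 (jejunum and ileum of DIO mice), 0 and 0 (ileum and colon of Obese mice) and 7 (difference between regions). Without the leading gene NAC gave 2. Thinned counts gave 602, 203, 118 and 2775 in human jejunum, ILC3, MNP and Th17, human jejunum libraries with fewer than 20000 genes detected (5 against 1) gave 0, and the deepest library per person gave 372 and 136 in ILC3 and MNP.

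With the identical columns kept, ILC3 gave 0 with palmitate, 84 with LPS and 28 with palmitate when stimulated, and MNP 13 with palmitate and 144 with LPS. In stimulated ILC3 with palmitate the direction then turned for Il22 (-0.23, adjusted p = 0.962), because the kept column titled stimulated palmitate 1 holds 68 counts of Il22. The 2 stimulated vehicle libraries hold 31211 counts of Il22 and the 3 vehicle libraries 170, which argues against that title. The direction also turned for Chad (1.04, adjusted p = 0.782), where the cause was not tested. The list calls for macrophage and monocyte genes (adjusted p = 0.298) and lymphocyte activation genes (adjusted p = 0.898) in MNP with LPS turned as well. The kept column titled MNP palmitate 4 holds 3 counts of Cd68 and 0 of Lyz2. Fits with it therefore do not measure how stable the MNP results are. No other named gene past the threshold and no other list call turned direction. Over the lists, 150 camera calls became 118 with the replicate block, 146 with RLE factors and 132 with no filter on low counts. Of 104 calls 79 remained with only the groups compared, of 106 calls 101 without the leading gene and of 19 calls 16 with the identical columns kept, and of the 150 calls 11 remained with an estimated correlation.

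The sample numbers were not taken to pair the samples. In no comparison with at least 3 pairs of equal numbers did every such pair correlate at over 0.1. With 2 pairs each, both did in duodenum (0.286 and 0.632) and ileum (0.1675 and 0.281) of DIO mice. In ileum at 1 week equal numbers correlated at 0.431 on average and different numbers at -0.0827. Pairing by number is therefore not excluded in these tissues. With the number as replicate block the counts were 13, 75 and 8 in duodenum, jejunum and ileum at 1 week, 77, 45 and 471 in duodenum, ileum and colon of DIO mice, 3, 145 and 4 in duodenum, ileum and colon of Obese mice, 3 for NAC, 13 in ILC3 with palmitate, 9 and 11 in Th17 with palmitate and with LPS, and 3 for the difference between regions. Leaving out each library in turn gave 3 to 8 and 2 to 42 in duodenum and jejunum at 1 week, 50 to 684, 5 to 203 and 0 to 6 in jejunum, ileum and colon of DIO mice, and 556 to 2723, 0 to 339 and 0 to 0 in those of Obese mice. It gave 0 to 10 for NAC and 0 to 1 for germ-free LPS. In human jejunum, ILC3, MNP and Th17 it gave 571 to 3943, 151 to 970, 21 to 359 and 1752 to 5838. In ILC3 it gave 0 to 17 with palmitate, 91 to 141 with LPS, 991 to 1455 when stimulated and 19 to 79 with palmitate when stimulated, in MNP 13 to 43 with palmitate, and in Th17 2 to 5 with palmitate, 3 to 7 with LPS, 14 to 33 when stimulated and 0 to 3 with palmitate when stimulated. Libraries with little background could not be fitted for duodenum of DIO or Obese mice, nor duodenum of Obese mice without its only library. Of the 248 genes named with a test, 239 were past the threshold as reported, 117 of them in every alternative that leaves out no library and 105 without any single library, and 242 kept their sign throughout.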

Other observations

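The splits of the samples given at the end of this part were tested after the results were seen. In jejunum of Obese mice further cell type genes moved, again with shares of cell types not separated from expression within cells. The stem cell gene Olfm4 fell by 2.38 ± 0.48 log2 units, the matrix genes Dcn and Col3a1 by 2.24 ± 0.34 and 2.11 ± 0.28, the B cell receptor genes Cd79b and Cd79a by 4.68 ± 0.69 and 3.20 ± 0.55, the Paneth cell ribonuclease gene Ang4 by 2.03 ± 0.50 and the replication gene Mcm5 by 1.92 ± 0.35. H2-Ab1 fell by 1.49 ± 0.41, Irf8, a transcription factor of dendritic cells, by 1.06 ± 0.26, and the endoplasmic reticulum genes Pdia4 and Hspa5 by 2.35 ± 0.26 and 1.98 ± 0.31. The gut hormone genes Sct and Gip rose by 1.99 ± 0.36 and 1.56 ± 0.27, Apoc3 by 2.85 ± 0.83 and Acaa1b by 3.09 ± 0.45. In jejunum of DIO mice Insig1, a sterol sensor, rose by 1.63 ± 0.34, Me1 by 2.03 ± 0.37 and the defence gene Reg3a by 1.74 ± 0.38, and the stem cell gene Smoc2 fell by 1.19 ± 0.26.

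In the palmitate experiment the stimulus also raised death and activation genes of ILC3, with Fas at 2.56 ± 0.32 log2 units, Casp4 at 1.67 ± 0.27, the inflammasome gene Nlrp3 at 2.44 ± 0.66 and the costimulatory gene Tnfrsf9 at 1.47 ± 0.14. In MNP, LPS raised the alarmin gene S100a8 by 1.81 ± 0.41 and the adhesion gene Cd44 by 0.49 ± 0.14 and lowered the Fc receptor gene Fcgr1 by 0.65 ± 0.18. In Th17 cells the stimulus raised Birc3 by 0.58 ± 0.14, Gbp4 by 0.52 ± 0.11, Irf1 by 0.49 ± 0.12 and Ltb by 0.36 ± 0.10, and lowered the costimulatory gene Cd28 by 0.43 ± 0.11. In ILC3 the fixed genes Il23r (-0.40 to 0.20) and Ahr (-0.20 to 0.83) were past the threshold in none of 4 comparisons, Il22 in 2 and Il17a in 1. In MNP Il23a held at most 6 counts in a group and was not tested, and in epithelial layers Gzmb held at most 32 counts.

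Each of the 30 lists was tested in up to 26 comparisons, 544 tests in all with 150 calls, given here as calls up and down over comparisons tested. Lipid lists gave 8 and 3 of 25 (fatty acid oxidation and ketogenesis), 6 and 1 of 24 (fat absorption and chylomicrons) and 2 and 3 of 24 (sterol and fatty acid synthesis). Defence lists gave 2 and 5 of 21 (antimicrobial and IL-22 target genes), 1 and 9 of 24 (MHC class II and interferon-gamma response), 0 and 3 of 20 (type I interferon response) and 3 and 0 of 24 (inflammatory cytokines and NF-kB response). Stress and growth lists gave 4 and 2 of 25 (oxidative stress and glutathione), 2 and 5 of 24 (ER stress and amino acid response), 1 and 1 of 24 (cell death), 1 and 7 of 24 (cell cycle), 3 and 6 of 25 (oxidative phosphorylation), 1 and 2 of 26 (glycolysis and hypoxia) and 3 and 5 of 24 (immediate early and heat shock). Lymphoid lists gave 2 and 0 of 21 (ILC3 and type 17), 0 and 1 of 8 (ILC1, NK and cytotoxic), 0 and 2 of 14 (T cell), 2 and 3 of 12 (B and plasma cell) and 2 and 2 of 21 (lymphocyte activation). Myeloid and stromal lists gave 1 and 7 of 16 (macrophage and monocyte), 1 and 1 of 14 (dendritic cell), 1 and 7 of 14 (stromal, muscle and vessel) and 0 and 1 of 5 (adipocyte). Epithelial lists gave 4 and 5 of 20 (epithelial cell), 0 and 3 of 14 (stem cell), 1 and 6 of 12 (Paneth cell), 0 and 1 of 13 (goblet cell), 0 and 0 of 8 (tuft cell), 3 and 2 of 14 (enteroendocrine cell) and 1 and 2 of 4 (pancreatic acinar cell).

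Other splits of the same samples into groups of the same sizes were fitted for comparisons with at least 3 samples a side, each with the real count, the number of splits as large, the real one included, and the highest other. The share of splits as large lay under 0.05 for jejunum at 1 week (9 genes, 1 of 100 splits, highest other 2), NAC (9, 1 of 56, highest other 7), MNP with palmitate (24, 1 of 56, highest other 20) and with LPS (482, 1 of 100, highest other 206). So did that of Th17 with LPS (4, 1 of 60, highest other 2). It also lay under 0.05 for Th17 with palmitate (4, 2 of 60, highest other 9), human ILC3 (637, 2 of 100, highest other 646) and duodenum at 1 week (8, 4 of 100, highest other 440). There at least 1 other split called more genes than the real one, which keeps this test from tying these 3 counts to treatment, obesity or diet. For stimulated Th17 with palmitate the share was not under 0.05 (2, 3 of 60, highest other 4). These shares were not adjusted over the comparisons, so that none of them excludes chance. With no gene called, every split was as large in ileum and colon at 1 week (100 of 100 each, highest others 3390 and 2951), epithelial layers at 1 and 12 weeks (40 of 40 each, highest others 52 and 1), the difference between regions (25 of 25, highest other 0) and the Th17 difference (60 of 60, highest other 3). In ileum, colon and duodenum at 1 week and in epithelial layers at 1 week some splits called many times the real count, which points to a structure of the samples. In ileum it followed the sample numbers, since in a comparison chosen after the results were seen 3825 of 11107 genes differed between numbers 1 to 3 and 4 to 6, with 18849 to 20362 genes detected in the first set and 25071 to 30885 in the second. In duodenum, jejunum and colon 5, 4 and 0 genes differed between these sets, and the structure in duodenum, colon and epithelial layers was not identified. A term for these sets gave 0 genes for diet in ileum and in colon. For germ-free LPS (0, 10 of 10 splits, highest other 58) and stimulated Th17 (44, 1 of 10, highest other 0) the splits were too few for a share under 0.05.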
